A study of Mus musculus with 3 samples.

How the data were processed

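The 3 libraries were made from bone marrow HSPCs of C57BL/6 mice with floxed Cic alleles and tamoxifen treatment. Per the labels' protocols, red blood cells were lysed, cells were enriched on beads through c-Kit, and those negative for CD4, CD8a, CD11b, B220, Gr-1 and Ter119 but positive for c-Kit and Sca-1 were sorted into TRIzol. Per the same protocols, complementary DNA was amplified from 10 ng of total RNA with the NuGEN Ovation system, primed both at poly(A) tails and at random, sheared to 400 bp inserts and sequenced on an Illumina HiSeq instrument. Such amplification makes many copies of each molecule, so counts are not independent molecules. Random priming also lets ribosomal RNA and unspliced RNA into the library.

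The deposited files hold raw read counts per gene symbol, 1 file per library, as whole numbers without normalization. The submitters' processing notes name TopHat2 2.0.9, HTSeq, DESeq2 and the mm10 build. The version of HTSeq and DESeq2, the gene model and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes could not be told apart. Each file has 24421 gene symbols, 92 ERCC spike-in entries and 5 HTSeq category entries. All entries summed to 80436738, 73572898 and 74995473 counts in libraries 1, 2 and 3. Of these, gene counts were 38.2%, 34.1% and 40.0%, alignments in no gene 43.5%, 48.4% and 42.9%, non-unique alignments 17.0%, 16.5% and 16.0%, and ambiguous ones 0.702%, 0.666% and 0.800%. The spike-ins and the category entries were left out of library sizes and tests. No mitochondrially encoded gene is listed, so the planned share of such genes gave no value. HTSeq with its default settings drops reads that align to several places, which lowers genes with near-identical copies.

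Counts were scaled to CPM by the total of gene counts times the TMM factor of edgeR (0.977, 1.02 and 1.00 for libraries 1, 2 and 3). Logs were taken as log2(CPM + 0.5), which understates differences of low genes. A gene with no count in a library enters its mean as 0, and the level such a 0 allows was set at 3 counts. Shares of counts have exact Clopper-Pearson 95% intervals. With a single group, no test between groups was possible, and 3 kinds of comparison were made. List medians were compared within each library by an exact two-sided sign-flip permutation test on 3 differences, which cannot give a p under 0.25. Counts of each gene were compared between libraries by a chi-square test with 2 degrees of freedom. Genes more variable than others of similar abundance were sought with edgeR's quasi-likelihood fit (intercept only, robust), by an F test of each gene's quasi-dispersion over the trend. Both gene tests covered genes with a mean of at least 1 CPM and used Benjamini-Hochberg adjusted p under 0.05. The shift of a list in a library was its median log2 difference from the mean of the other libraries, placed among 10000 random lists of the same size drawn from 20 bins of mean expression.

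The main tests, the alternatives, 24 gene lists and the rule for naming genes were fixed before the data were examined, but not the adjustment of the variability test over the list genes alone. The rule took Cic, up to 5 highest and 2 lowest members of each list, members past the variability test, the 20 most abundant genes, and the 25 genes of largest log2 range among those past the variability test with a mean of at least 5 CPM. Only Elane passed that test over all genes, and list members that passed over the list alone were named as well. The 25 genes of largest range were therefore taken without it, and those named in the closing section from outside the lists were chosen after their values were seen. Of 238 listed genes, 236 have an entry (Ly6g and Ahsp do not) and 196 reached a mean of 1 CPM. Lists share some genes, such as Egr1, Itgam and Cd4. Values of some list members that the rule would name are not reported here.

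Coordinates, exon lengths, GC content and the share of 50-base words that a gene's transcripts have in common with other genes came from the GENCODE M21 annotation of GRCm38, the assembly of mm10, to which 98.2% of gene symbols were matched. The alternatives were DESeq2 size factors and plain totals, other pseudocounts, other expression minima, totals without ribosomal protein genes or without Rn45s, CPM per kilobase, other edgeR settings, a DESeq2 dispersion and leaving out each library in turn. Totals without Rn45s were added after the data were seen. Software was R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1, and Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

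Both gene tests were tested on simulated data. For the variability test, counts were drawn in 5 runs from the means and trend dispersions of the real libraries, with 200 genes changed in 1 library. On 12802 to 12845 genes it recovered 49.2% of genes changed 2-fold, 90.8% at 4-fold, 97.2% at 8-fold and 100% at 16-fold, and 19 of 862 calls (2.20%) were false. The simulation had no gene-to-gene scatter around the trend, so these shares need not hold for the real libraries. On 12967 genes the chi-square test recovered 84 of 100 genes changed 1.5-fold and 97 of 100 changed 2-fold, with 5 false calls. These counts were drawn with read-counting noise alone, which the test itself assumes. Its false calls on amplified libraries were not measured.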

Results

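RNA of hematopoietic stem and progenitor cells (HSPCs) from mouse bone marrow was sequenced in 3 control libraries, numbered 1 to 3 by the replicate number in their titles. HSPCs are the rare marrow cells from which all blood lineages arise, and here they were sorted as cells without lineage markers that carried c-Kit and Sca-1 on their surface. The mice were C57BL/6 with both Capicua (Cic) alleles flanked by loxP sites, and they had been given tamoxifen, the drug that switches on inducible Cre recombinases. Capicua is a transcriptional repressor that is released from its targets by MAPK signalling, and the study concerned its loss in early T cell development and T cell leukaemia. The series compared 2 mouse groups. The other group was not analysed here, so the values below are the baseline of the control cells, with no contrast between genotypes. The gene counts came to 30718562, 25097769 and 30032593 in libraries 1, 2 and 3. At least 1 count was found for 15798, 16159 and 16410 genes, and 12967 genes reached a mean counts-per-million value (CPM) of at least 1. Gene values are mean CPM ± SD over the 3 libraries. A count of 0 allows from 0.0997 to 0.117 CPM, depending on the library (3 counts each), and these floors and the share intervals below cover counting error only.

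Capicua itself was well expressed in every control library. Cic (chromosome 7, 25267704 to 25294159, mm10 coordinates from GENCODE M21, ENSMUSG00000005442.13) was counted 5158, 3500 and 3601 times in libraries 1, 2 and 3, or 172, 137 and 119.6 CPM. Its mean was 143 ± 26.6 CPM, rank 1483 among all genes. The counts cover the whole gene, so they cannot show the state of the flanked exons. The partners of Capicua in its repressor complex were also expressed, Atxn1 at 133 ± 28.6 CPM and Atxn1l at 63.8 ± 11.5 CPM. Atxn2, which was listed with them but is not taken as a partner here, lay at 90.6 ± 3.44 CPM. All 4 genes of this list passed 1 CPM, with a list median of 112 CPM.

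Genes of the Capicua target and MAPK feedback list lay lower. In this list of 13 genes, 11 reached 1 CPM and the median member lay at 10.98 CPM. Of the PEA3-family ETS factors, the best known Capicua targets, Etv5 was at 31.1 ± 8.56 CPM, Etv1 at 2.98 ± 1.35 CPM and Etv4 at 0.449 ± 0.494 CPM (3, 26 and 7 counts). Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, was at 0.853 ± 0.644 CPM. The highest members were the MAPK feedback inhibitor Spred1 at 103 ± 6.55 CPM, its relative Spred2 at 52.5 ± 10.6 CPM, the ERK phosphatase gene Dusp6 at 42.6 ± 1.66 CPM and the G1 cyclin gene Ccnd1 at 42.2 ± 4.96 CPM. None of the 11 members at 1 CPM or more was more variable than genes of its abundance after adjustment with edgeR, and Etv4 and Spry4 were not tested.

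Genes of the sort markers and of stem cells were expressed in every library. Kit, the receptor used for enrichment, lay at 827 ± 86.4 CPM and Ly6a, which encodes Sca-1, at 103 ± 9.13 CPM. All 16 stem cell genes reached 1 CPM, with a median of 24.8 CPM. Among the highest were Hlf, a transcription factor of long-term stem cells, at 680.5 ± 124 CPM, Meis1 at 261 ± 23.6 CPM, Gata2 at 128 ± 19.0 CPM and Mecom at 121 ± 7.46 CPM. The lowest were Hoxb5 at 3.96 ± 0.641 CPM and Ndn at 2.34 ± 0.760 CPM.

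Lymphoid-primed progenitor genes were abundant. All 12 of them reached 1 CPM, and their median of 165 CPM was the highest of the 11 lists set against the stem cell genes. Cd34 lay at 425 ± 0.900 CPM, Dntt, the terminal transferase of antigen receptor rearrangement, at 359 ± 12.3 CPM, the cytokine receptor gene Flt3 at 354 ± 30.5 CPM and the chromatin organiser gene Satb1 at 326 ± 53.7 CPM. The thymus-homing receptors were lower, with Ccr9 at 10.4 ± 1.31 CPM and Ccr7 at 2.99 ± 0.781 CPM. In log2(CPM + 0.5) the stem cell median lay 1.97 below the lymphoid-primed median (SD 0.08, lower in 3 of 3 libraries, exact two-sided sign-flip p = 0.25, the smallest that 3 libraries allow, and 0.275 after Benjamini-Hochberg adjustment over 11 list comparisons). Per kilobase of annotated exons the gap was 0.77, since CPM also grows with transcript length.

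Granulocyte-monocyte progenitor genes were expressed, unevenly between the libraries. Of 12 such genes, 11 reached 1 CPM, with a median of 42.5 CPM. Mpo, the myeloperoxidase gene of early granulocyte and monocyte precursors, was at 1536 ± 849.9 CPM and ranked 28 among all genes, Csf3r, the G-CSF receptor gene, at 253 ± 32.5 CPM, and the granule protease genes Elane, Ctsg and Prtn3 at 125 ± 108, 94.3 ± 53.3 and 79.5 ± 28.1 CPM. The lowest were the Fc receptor gene Fcgr3 at 2.49 ± 1.91 CPM and the late granulocyte factor gene Cebpe at 0.428 ± 0.149 CPM. The stem cell median lay 0.57 (SD 0.71) below that of this list in log2(CPM + 0.5), lower in 2 of 3 libraries (exact p = 0.5), so the lists did not separate beyond the spread between libraries. Leaving out 1 library moved this difference to between -0.96 (without library 1) and -0.25 (without library 3), and it was -0.33 per kilobase of exons and -0.93 over members with a mean of at least 1 CPM.

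The megakaryocyte-erythroid program was low apart from a few genes. Car2, a carbonic anhydrase gene, lay at 473 ± 36.1 CPM, Car1 at 58.4 ± 40.9 CPM, the Gata1 cofactor gene Zfpm1 at 39.3 ± 5.34 CPM, Itga2b, which encodes CD41, at 24.2 ± 6.09 CPM and Gfi1b at 23.2 ± 2.00 CPM. Of 12 genes 10 reached 1 CPM, and Gp6, a platelet collagen receptor gene, had no count in any library. Gp1bb was at 0.579 ± 0.256 CPM, but it shares 90.6% of its 50-base sequence words with other annotated genes, so its count is uncertain. The list median was 6.63 CPM, and the stem cell median lay above it by 1.76 (SD 0.28) in 3 of 3 libraries (exact p = 0.25, the smallest possible), a gap of 0.40 per kilobase of exons and 0.88 over members with a mean of at least 1 CPM.

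Genes of mature cells were mostly low. Of 11 T and NK cell genes, 5 reached 1 CPM and the median was 0.871 CPM. The T cell receptor complex genes Cd3e (0, 0 and 2 counts) and Cd3g (1, 0 and 4 counts) lay near or below the floor. Cd3d of the same complex, named outside the rule, had 22, 0 and 36 counts in libraries 1, 2 and 3. Nkg7, a granule gene of cytotoxic cells, was at 90.2 ± 8.18 CPM, Lck at 13.7 ± 1.77 CPM and Cd4 at 9.05 ± 5.71 CPM. Of 10 macrophage and dendritic cell genes, 7 reached 1 CPM (median 1.46 CPM), led by Cd68 at 28.5 ± 7.22 CPM, with C1qa at 0.115 ± 0.0739 CPM and Adgre1 at 0.290 ± 0.218 CPM. Of 10 stromal and endothelial genes, 4 reached 1 CPM (median 0.594 CPM), led by Lepr at 6.84 ± 0.334 CPM and Col1a2 at 5.60 ± 2.70 CPM, and Col3a1 and Adipoq had no count in any library. B cell genes were somewhat higher, with 8 of 9 at 1 CPM or more and a median of 7.93 CPM. Their highest members were the receptor chain genes Cd79b at 24.6 ± 2.10 CPM and Cd79a at 11.6 ± 1.13 CPM, the surrogate light chain gene Igll1 at 20.03 ± 1.79 CPM and the B lineage factor gene Ebf1 at 11.4 ± 2.27 CPM. All 7 mast cell and basophil genes reached 1 CPM (median 5.20 CPM), led by the carboxypeptidase gene Cpa3 at 29.1 ± 1.03 CPM.

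Neutrophil genes spread more between the libraries, with an SD of the list median of 0.80 in log2, against 0.03 to 0.26 for the B cell, T and NK cell, macrophage, mast cell and stromal lists. Of 10 genes 9 reached 1 CPM, with a median of 11.1 CPM. Itgam, which encodes the sort marker CD11b, lay at 138 ± 11.1 CPM (an uncertain count, as 66.3% of its 50-base words are shared with other genes), the granule protein gene Ngp at 43.7 ± 34.5 CPM, S100a9 at 23.3 ± 13.3 CPM, Lcn2 at 16.3 ± 10.7 CPM and S100a8 at 13.3 ± 7.44 CPM. Of the 7 lineage cocktail genes measured, 5 reached 1 CPM, with a median of 9.05 CPM. Ptprc was at 357 ± 19.2 CPM, Ly6c2 at 16.6 ± 13.5 CPM, and Cd8a and Ly6c1 at 0.346 ± 0.143 and 0.326 ± 0.166 CPM (32.8% of words shared for Ly6c1). Ptprc encodes all forms of CD45, of which the B220 antibody binds only 1 form. Of 9 mature erythroid genes 3 reached 1 CPM. Alas2, the haem synthesis gene, was at 11.3 ± 2.90 CPM and Slc4a1 at 5.79 ± 6.70 CPM, and all 10 haemoglobin genes were listed at 0.

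The stem cell median lay above the medians of the B cell, neutrophil, lineage cocktail, mast cell and basophil, macrophage and dendritic cell, T and NK cell, and stromal and endothelial genes in 3 of 3 libraries. In log2(CPM + 0.5) the gaps were 1.60 (SD 0.36), 1.32 (SD 0.66), 2.08 (SD 0.42), 2.28 (SD 0.52), 3.73 (SD 0.42), 3.90 (SD 0.43) and 4.71 (SD 0.29) in that order. Each of these 7 comparisons gave an exact p of 0.25, the smallest possible with 3 libraries, and 0.275 after Benjamini-Hochberg adjustment over 11. Over members with a mean of at least 1 CPM, the gaps for lineage cocktail, T and NK cell, and stromal and endothelial genes were 0.41, 1.58 and 2.88, the first of these higher in only 2 of 3 libraries (exact p = 0.5), and per kilobase of exons those for neutrophil and for mast cell and basophil genes were 0.75 and 1.03. The comparison with the mature erythroid genes, the last of the 11, decides nothing, since 6 of 9 members are at 0 and the gap (5.67, SD 0.27) is set by the pseudocount (4.70 with 1 and 7.97 with 0.1).

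**Figure D1:**
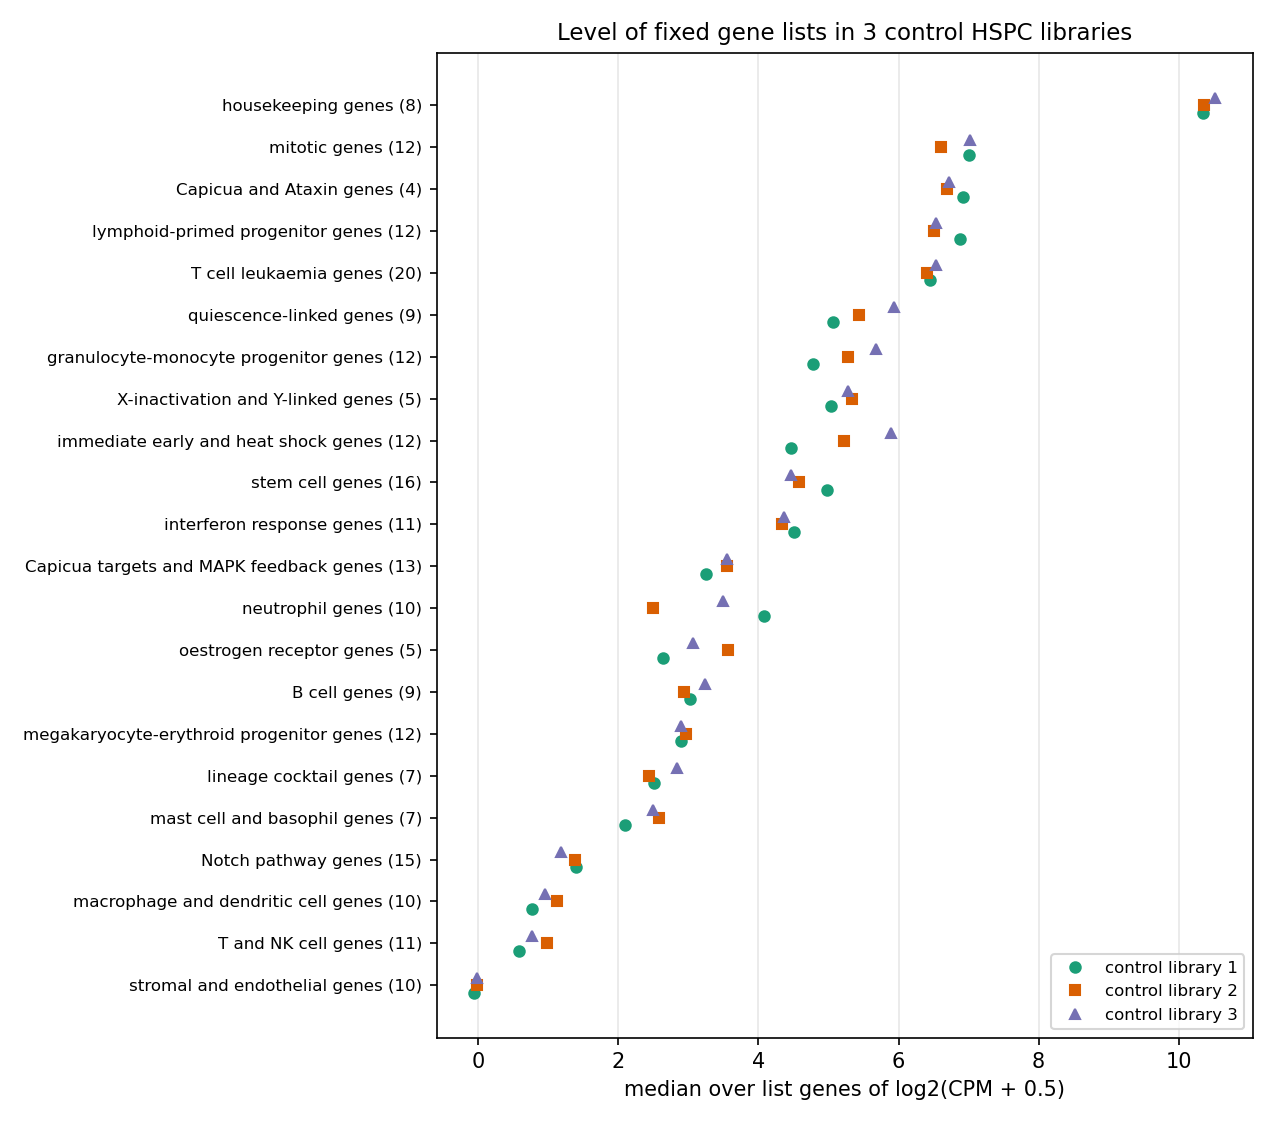
Level of 22 fixed gene lists (all but the sort markers and the mature erythroid genes), with the number of measured members in parentheses, in each control library. The horizontal axis is the median over members of log2(CPM + 0.5), each symbol is 1 library, and symbols of a list are offset vertically for legibility. Lymphoid-primed genes (6.64 ± 0.21, SD) lie above stem cell genes (4.67 ± 0.27), which lie above B cell genes (3.07 ± 0.15) and T and NK cell genes (0.78 ± 0.20).

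Notch signalling drives T cell specification. Of its receptor genes, Notch2 lay at 382 ± 36.7 CPM and Notch1 at 142 ± 27.0 CPM, while Notch3 and Notch4 lay at 3.22 ± 1.34 and 2.75 ± 1.00 CPM, with the DNA-binding partner gene Rbpj at 153 ± 2.97 CPM and the coactivator gene Maml1 at 56.9 ± 8.71 CPM. The targets Nrarp and Hes1 were at 3.39 ± 2.23 and 1.06 ± 0.617 CPM, Hey1 (0, 2 and 3 counts) and Dtx1 (0, 1 and 0 counts) lay at or below the floor, and Ptcra, the pre-T cell receptor gene, was at 0.239 ± 0.125 CPM. Notch3, Notch4, Hes1 and Ptcra fall outside the naming rule and were chosen after their values were seen. Of 15 Notch pathway genes 10 reached 1 CPM, with a median of 2.75 CPM.

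Most genes linked to T cell leukaemia were expressed in the control HSPCs. Of 20 such genes 17 reached 1 CPM, with a median of 88.0 CPM. Among the highest were Myb at 992 ± 38.6 CPM, Ikzf1, which encodes Ikaros, at 661 ± 17.0 CPM, Myc at 553 ± 18.1 CPM and Lmo2 at 519 ± 30.0 CPM. The homeobox genes Tlx1 and Tlx3, which translocations switch on in T cell leukaemia, had no count in any library.

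Mitotic genes were abundant in all 3 libraries. All 12 reached 1 CPM, with a median of 117 CPM. Mki67, a marker of dividing cells, lay at 1791 ± 187 CPM, the topoisomerase gene Top2a at 959.6 ± 88.0 CPM, the spindle motor gene Kif11 at 301 ± 22.1 CPM, Ccna2 at 198 ± 14.6 CPM and Cenpf at 182 ± 18.2 CPM. Quiescence-linked genes were expressed beside them, with 9 of 9 at 1 CPM or more and a median of 48.3 CPM, including Txnip at 421 ± 81.1 CPM, Foxo3 at 175 ± 20.2 CPM, the retinoblastoma gene Rb1 at 63.0 ± 3.34 CPM and Btg2 at 48.3 ± 20.6 CPM. The CDK inhibitor gene Cdkn1c was at 5.28 ± 2.97 CPM and Klf4 at 6.19 ± 3.46 CPM. Immediate early genes, which respond to stimulation within minutes and also to cell handling, were listed with heat shock genes. Of these 12 genes 10 reached 1 CPM, with a median of 42.4 CPM, Egr1 at 316 ± 193 CPM, Zfp36 at 158 ± 62.9 CPM, Jun at 126 ± 56.1 CPM, Dusp1 at 112 ± 22.2 CPM and Fos at 81.4 ± 43.2 CPM. Atf3 was at 0.118 ± 0.105 CPM and the heat shock gene Hspa1b at 0.833 ± 0.382 CPM, an uncertain count, as 62.3% of its 50-base words are shared with other genes.

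All 11 interferon response genes reached 1 CPM, with a median of 17.96 CPM, among them Oas1a at 26.7 ± 4.37 CPM, Ifit1 at 25.2 ± 3.05 CPM and Ifit3 at 3.11 ± 1.35 CPM. Oas1a and Ifit3 share 57.6% and 51.2% of their words with other genes, so their counts are uncertain. Tamoxifen binds oestrogen receptors, and Esr1 was expressed at 52.9 ± 4.14 CPM, its target genes Pgr and Greb1 at 42.1 ± 5.80 and 8.33 ± 2.86 CPM, and Esr2 had 0, 0 and 5 counts (4 of 5 such genes at 1 CPM or more, median 8.33 CPM). Xist, the RNA of the inactive X chromosome, lay at 6287 ± 208 CPM, and the Y-linked genes Kdm5d, Eif2s3y, Ddx3y and Uty were all counted too, at 47.3 ± 7.04, 35.0 ± 3.61, 32.5 ± 7.35 and 27.4 ± 2.07 CPM. The 8 housekeeping genes had a median of 1359.9 CPM. Eef1a1 lay at 6024 ± 68.4 CPM, B2m at 3505 ± 364 CPM, Actb at 2369 ± 226 CPM, Gapdh at 1433 ± 86.1 CPM and Ppia at 1287 ± 112 CPM, with Hprt at 144 ± 0.940 CPM and Tbp at 85.1 ± 6.02 CPM.

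The most abundant transcript was Rn45s, the precursor of ribosomal RNA, with 11.8%, 8.20% and 7.91% of gene counts in libraries 1, 2 and 3 (exact Clopper-Pearson 95% intervals 11.81 to 11.83, 8.19 to 8.21 and 7.90 to 7.92%). It was followed by Lars2 at 11133 ± 1544 CPM, the nuclear RNA Malat1 at 9315 ± 1046 CPM, Xist, Eef1a1 and B2m. Lars2 was at 12916, 10221 and 10262 CPM in libraries 1, 2 and 3, highest in library 1 like Rn45s. Rn45s has no position in the annotation used, so words that Lars2 may share with it were not checked. The Lars2 count is therefore uncertain. The other members of the top 20 were the translation genes Pabpc1, Eef2 and Eif4g2, the ribosomal protein genes Rpl4, Rps6, Rpl10a and Rpl10, the chaperone genes Hspa8 and Hsp90ab1, Npm1, Serinc3, Actb, Mki67 and Srrm2. Rps6, Eef1a1, Hspa8 and Rpl10 share 43.8%, 39.4%, 38.6% and 33.5% of their 50-base sequence words with other annotated genes, so their counts are uncertain. The 20 genes held 16.03 ± 2.27% of gene counts, and without Rn45s the share was 7.42%. The 100 ribosomal protein genes held 4.93 ± 0.618%, and the haemoglobin genes 0 of 25097769 or more counts in each library (exact Clopper-Pearson 95% upper limit at most 1.47e-05%).

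How far the control libraries differed from each other sets the error of any comparison with them. A chi-square test on the counts found 10676 of 12967 genes (82.3%) to differ beyond counting noise after Benjamini-Hochberg adjustment, among them Cic. By pairs the number was 8283 for libraries 1 and 2, 8681 for libraries 1 and 3, and 6688 for libraries 2 and 3, so each pair differed beyond read-counting noise, a low bar for amplified reads. Library 1 stood farther from the others, with 640 and 670 genes over 2-fold apart from libraries 2 and 3, against 303 between libraries 2 and 3. Across genes, which are not independent replicates, Spearman's rho was 0.983, 0.981 and 0.990 for these pairs. The biological coefficient of variation from edgeR was 20.7%, and without library 1 it was 15.1%. Over all settings it ran from 12.2% (median gene-wise dispersion of DESeq2) to 26.5% (no expression filter). The labels do not say that the libraries came from separate animals, so the differences between them may be technical. The chi-square test measures departure from read-counting noise only, not the spread expected between animals.

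Elane, the neutrophil elastase gene (chromosome 10, 79886247 to 79888215, mm10), was the 1 gene whose spread exceeded that of genes of similar abundance. It was counted 759, 2813 and 7202 times in libraries 1, 2 and 3, or 25.3, 109.7 and 239 CPM, a 9.46-fold range (edgeR quasi-dispersion test with Benjamini-Hochberg adjustment over 12967 genes, adjusted p = 0.0191). At an unadjusted p under 0.05 there were 589 genes (4.54%), a share no larger than that threshold itself, so they are no excess of variable genes. Leaving out library 1, 2 or 3 gave 33, 9 and 9 genes, each time with Elane among them.

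Of the 196 list genes tested, 38 had an unadjusted p under 0.05 and 19 passed when adjusted over the list alone, against 1 over all genes. The lists were fixed beforehand, but this second adjustment was not in the fixed plan. Of these 19, 5 were granulocyte-monocyte progenitor genes (Elane, Mpo, Ctsg, Prtn3 and Ms4a3), 4 were neutrophil genes (Ngp, S100a8, S100a9 and Lcn2) and 6 were immediate early genes (Egr1, Fos, Fosb, Jun, Zfp36 and Nr4a1). The remaining 4 were Ly6c2, Btg2, Car1 and the erythrocyte anion exchanger gene Slc4a1, at 13.5, 1.40 and 2.46 CPM in libraries 1, 2 and 3. Nr4a1, an orphan nuclear receptor gene, was at 1.77, 2.65 and 16.6 CPM, and Egr1 at 160.0, 255 and 532 CPM. For these 3 genes the edgeR adjusted p was 0.608, 0.415 and 0.115 over all genes and 0.0144, 0.00856 and 0.00232 adjusted over the list alone. Members outside the highest 5 of their lists were named because they passed over the list alone, which goes beyond the fixed naming rule.

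Members of several gene lists lay higher or lower together in a library. The granulocyte-monocyte progenitor genes had a median 1.04 lower in library 1 than in the mean of the others (log2, below all 10000 random lists matched on expression) and 0.75 higher in library 3 (above all of them). Mpo was at 699, 1512 and 2398 CPM and Ctsg at 40.7, 94.8 and 147 CPM in libraries 1, 2 and 3. Of the 12 progenitor genes, 9 were lowest in library 1, while Csf3r, Gfi1 and Cebpe were highest there. The immediate early and heat shock genes lay 0.98 lower in library 1 and 0.93 higher in library 3, with 12 of 12 members lowest in library 1 and 12 of 12 highest in library 3. Jun was at 66.7, 132 and 178 CPM. Neutrophil genes went another way, 1.17 higher in library 1, with 8 of 10 members highest there, and 1.37 lower in library 2, with 10 of 10 lowest there. Ngp was at 82.0, 15.1 and 34.1 CPM. Library 1 also had the highest shares of Rn45s (11.8%) and of ERCC spike-ins (1.46%), and library 3 the lowest (7.91% and 0.579%). The progenitor shift in library 3 was 0.46 without library 1 and 1.15 without library 2, the neutrophil shift in library 1 was 0.59 without library 2 and 1.80 without library 3, and the immediate early shift in library 1 was -0.43 without library 3.

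Stem cell genes were shifted less, 0.24 higher in library 1 and 0.26 lower in library 3, with 9 of 16 members highest in library 1 and Hlf at 821, 633 and 587 CPM. Without library 3 the first of these was 0.16, inside the central 95% of random lists, and without library 1 the other was -0.17. The Capicua and Ataxin genes lay 0.43 higher in library 1, where 3 of 4 members were highest and Atxn2 was lowest. They lay 0.25 lower in library 3, which became -0.02 without library 1 and -0.48 without library 2. Mitotic genes lay 0.17 lower in library 2 and 0.17 higher in library 3, and the latter was 0.04 without library 2. Also outside the central 95% of random lists were the megakaryocyte-erythroid and the mast cell and basophil genes in library 1 (-0.44 and -0.58), the lymphoid-primed genes in library 2 (-0.14), the granulocyte-monocyte progenitor genes in library 2 (0.13) and the Notch pathway genes in library 3 (-0.22). Each of these shifts but that of the progenitor genes fell inside the central 95% when 1 library was left out, and that of the progenitor genes was -0.46 without library 1. In all, 17 of 69 combinations of list and library lay outside the central 95%, against 3.45 for lists of unrelated genes. Genes of a list can move together, and the 3 shifts of a list depend on each other, so this excess is no test of chance. The percentiles describe these 3 libraries, carry no p-value, and give the replicates no order.

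**Figure D2:**
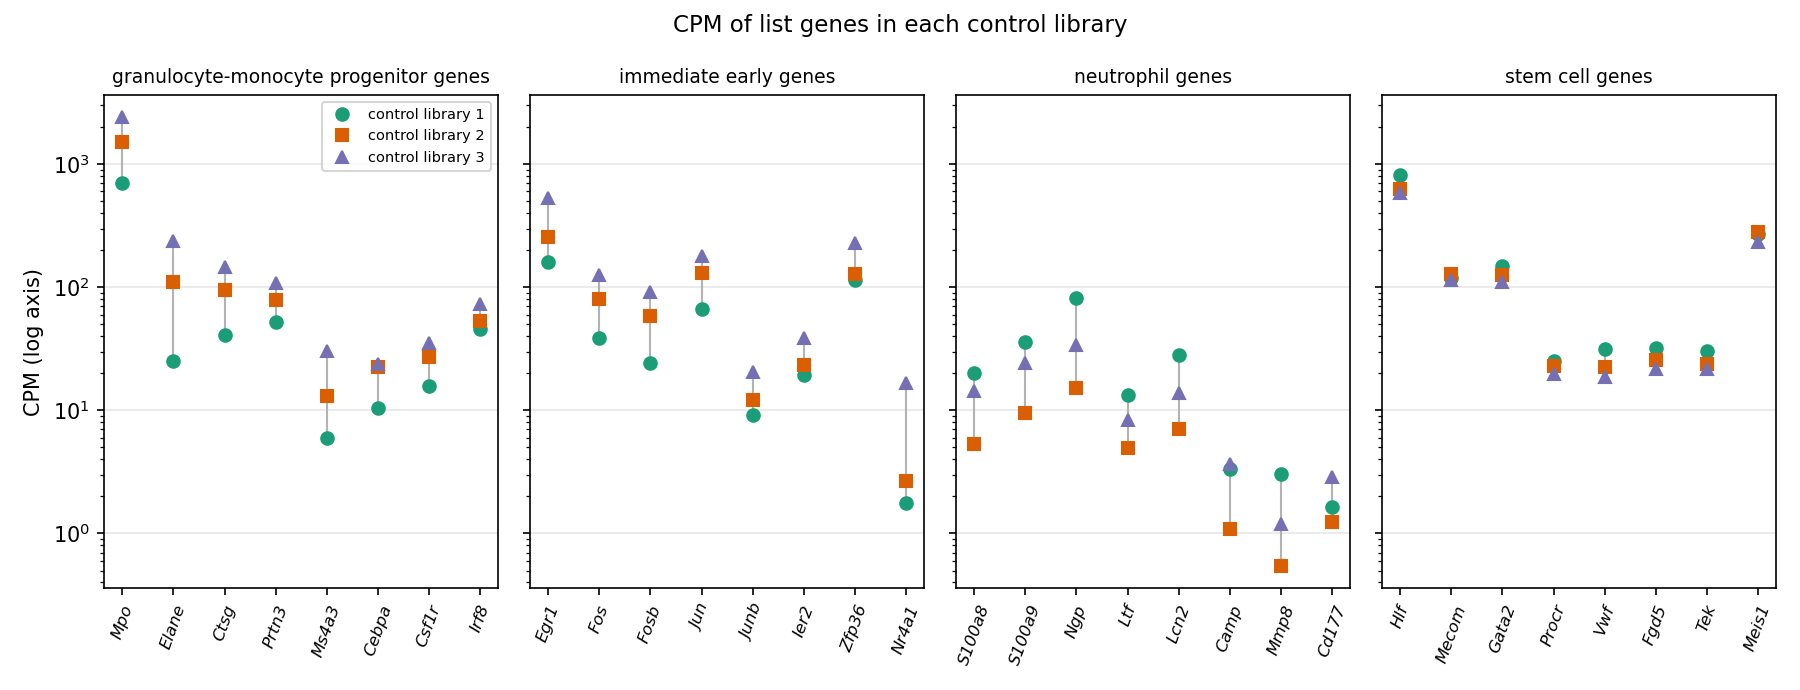
CPM on a log axis of 8 genes from each of 4 lists in the 3 control libraries. Each symbol is 1 library, and each grey line joins the lowest and highest of them. The genes shown follow no stated rule and make some lists look more uniform than they are. Left out are Csf3r, Gfi1 and Cebpe, the 3 progenitor genes highest in library 1. Over the full lists, 9 of 12 progenitor genes were lowest in library 1 and 9 of 16 stem cell genes highest there. Elane spans 25.3 to 239 CPM and Mpo 699 to 2398 CPM, both lowest in library 1 and highest in library 3, whereas Ngp spans 15.1 CPM in library 2 to 82.0 CPM in library 1.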

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

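The tests of neutrophil genes, of X-linked copies, of male and female RNA and of erythroid genes were chosen only after the result was seen, and the others were set before. Chance was not tested by regrouping samples, since there is a single group.

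Counts outside the main measurement drew attention in every library, far above what a count of 0 allows. ERCC spike-ins made up 1.46%, 0.945% and 0.579% of gene and spike-in counts in libraries 1, 2 and 3, a 2.53-fold range. Alignments in no annotated gene made up 43.5%, 48.4% and 42.9% of all counted alignments.

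Granulocyte-monocyte progenitor genes such as Elane, Mpo and Ctsg were lowest in library 1 for 9 of 12 members and highest in library 3 for 9 of 12. The other 3, Csf3r, Gfi1 and Cebpe, were highest in library 1, Csf3r at 290, 238 and 231 CPM in libraries 1, 2 and 3. The median log2 ratio of library 3 to library 1 was 1.17 over the 11 of 12 genes with GC content and length. Mature neutrophils left in the sort would bring their own transcripts, yet over the 10 neutrophil genes that ratio was -0.592 (bootstrap over genes -1.13 to -0.0051), with Ngp at 82.0 and 34.1 CPM in libraries 1 and 3. After the trend on GC content and exon length was removed, the progenitor ratio was 1.20 (0.67 to 2.16), so that trend is not the whole cause. A difference in the share of myeloid-primed cells between the marrow samples or sort gates stays open and was not tested, as the labels give no day, batch or animal. A technical difference between the libraries stays open as well and cannot be told apart from it. ERCC spike-ins fell from 1.46% to 0.945% and 0.579% over libraries 1, 2 and 3. All 12 immediate early and heat shock genes were lowest in library 1.

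Xist and 4 Y-linked genes were counted in every library, although Xist marks female cells and Y-linked genes male cells, and the Y-linked sum was 2.15%, 2.48% and 2.15% of Xist in libraries 1, 2 and 3. Reads of X-linked copies placed on their Y-linked partners would be limited to stretches that both share, but in the lowest library Ddx3y, Eif2s3y, Kdm5d and Uty reached 4.37%, 8.21%, 31.6% and 13.0% of the count of their X-linked partners. They hold only 1.61%, 0.317%, 0.181% and 1.48% of those partners' 25-base words, a ratio of 2.71 or more, which argues against such reads as the whole source. A planned test on Usp9y and Zfy1, which had no count, decides nothing, since a 0 in these counts is not evidence of silence. RNA of both male and female cells in each library is a candidate explanation that stays open, since the lowest count among Xist and the 4 genes, 702, only restates the pattern. Pooled animals of both sexes and carry-over between samples cannot be told apart here, as the labels give no sex.

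All 10 haemoglobin genes were listed at 0 in marrow cells. Alas2 and Slc4a1, whose lowest count was 36, argue against a complete absence of erythroid RNA. They do not show that cells with haemoglobin RNA were in the sort, so a lack of such cells stays open. Loss of reads shared between near-identical genes is possible. Protein-coding genes were at 0 in 90.8% of 271 cases with at least 95% of 50-base words shared against 24.3% of 20205 others, a ratio of 3.74, and in 65.2%, 47.1% and 19.7% of cases with 75 to 95%, 50 to 75% and under 1% shared. Whether the genes with many shared words are expressed in these cells was not tested, so the ratio alone does not show lost reads. Such a loss cannot be told apart from other causes, also because Hba-a2, Hba-a1, Hbb-bt and Hbb-bs share 89.3%, 72.3%, 58.3% and 53.2% of their words, short of 95%. Hbb-b1 and Hbb-b2 are not in the annotation used. Hba-x, Hbb-bh1, Hbb-bh2 and Hbb-y share none. Whether marrow cells transcribe these last genes at all was not tested, so their 0 does not count against a loss of shared reads. Rpl26, Atp6v0c and Ndufs5, genes that every cell uses, were also at 0 with 22.7%, 10.8% and 21.7% of words shared, so a 0 in these counts is not evidence of silence.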

How the results depend on the processing

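The totals without Rn45s were chosen after the result was seen, and every other setting was planned. The count of genes beyond counting noise (10676) was 6695 (without library 1) to 8681 with 1 library left out, where 1 degree of freedom remains. The count of variable genes (1) was 9 to 33 with 1 library left out, where the prior degrees of freedom of the test also rose. It was 1 in every other setting, and Elane was called in all settings. The biological coefficient of variation (20.7%) was 15.1 to 23.8% with 1 library left out, lowest without library 1, 26.5% with no expression filter, 14.3% at a mean of at least 10 CPM and 12.2% from the median gene-wise dispersion of DESeq2. The share of the 20 most abundant genes (16.03%) was 7.42% without the single most abundant gene, by construction. The shift of granulocyte-monocyte progenitor genes in library 2 (0.13) was reversed without library 1 and ran from -0.456 to 0.915 with 1 library left out, as the library lies between the others. The cause of the other moves was not tested. No mean list difference changed direction in any setting. Counting each single-gene or single-list result once per setting, 1802 stayed as they were, 144 moved by more than the spread between libraries, 67 of them with totals without Rn45s, and 11 shifts fell back inside the central 95%. No paired analysis was possible because there is only 1 group. Genes under about 0.1 CPM cannot be told from 0 at this depth.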

Other observations

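The genes in the paragraphs below that belong to no fixed list were chosen after their values were seen, and no test was planned for them. Mast cell and basophil genes did not move as one between the control libraries. The mast cell protease genes Mcpt4, Cma1 and Tpsb2 were highest in library 1, Mcpt4 at 12.5, 2.18 and 1.89 CPM, Cma1 at 8.10, 2.69 and 4.05 CPM and Tpsb2 at 6.60, 2.57 and 1.69 CPM in libraries 1, 2 and 3. The basophil protease genes Mcpt8 and Prss34 and the eosinophil peroxidase gene Epx were lowest in library 1, Mcpt8 at 1.63, 5.50 and 9.60 CPM, Prss34 at 2.999, 7.57 and 5.71 CPM and Epx at 1.33, 7.84 and 7.28 CPM. Hdc, the histamine synthesis gene, was at 3.17, 7.18 and 13.1 CPM, and of the genes common to both cell types, Fcer1a was at 0.766, 3.75 and 4.05 CPM, Ms4a2 at 3.77, 6.67 and 5.15 CPM and Cpa3 at 29.8, 29.5 and 27.9 CPM, so that 2 of these 3 were also lowest in library 1. None of these genes passed the edgeR variability test after adjustment over all genes.

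Further genes were picked by eye from the 25 of largest range, with no enrichment test behind them. Ptgs2, which encodes cyclooxygenase-2, and the nuclear receptor gene Nr4a2 were highest in library 3 beside the immediate early genes, Ptgs2 at 1.10, 2.85 and 11.2 CPM and Nr4a2 at 2.23, 4.88 and 14.9 CPM in libraries 1, 2 and 3. The monocyte-linked genes F13a1 and Ly6c2 were lowest in library 1 like Elane, F13a1 at 17.6, 41.5 and 71.1 CPM and Ly6c2 at 5.20, 13.3 and 31.5 CPM. Erdr1, Mid1 and G530011O06Rik were lowest in library 3, Erdr1 at 48.7, 80.1 and 10.3 CPM, Mid1, a gene at the pseudoautosomal boundary of the X chromosome, at 7.06, 12.4 and 1.79 CPM and G530011O06Rik at 4.998, 14.4 and 2.59 CPM. G530011O06Rik (X chromosome, 169975043 to 169978917, mm10) lies within the span of Mid1 (169685199 to 170005736), and the 2 genes share 14.8% and 15.0% of their 50-base words with other genes, so they need not be independent. Erdr1 has no position in the annotation used. Other genes of the 25 have no stated link to these, among them 1700024P16Rik, Adam4, Rrp9 and Tmem101, all lowest in library 1, and Cyp2t4, highest there.

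After scaling on their own totals, the ERCC spike-ins, which are added as purified RNA, varied about as little as the quietest sets of genes. The 37 spike-ins with a mean count of at least 100 had a coefficient of variation of 11.8%, against a median of 16.4% (range 10.5 to 27.0%) over 100 sets of genes matched on count, of which 4 lay at or below the spike-ins. Scaling the spike-ins on their own totals removes the 2.61-fold range of total spike-in counts between the libraries. The genes were scaled on TMM-adjusted totals of all genes, so the spike-in and gene values are not strictly comparable.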
